A study of Homo sapiens with 12 samples.

How the data were processed

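RNA from HEK 293T cells was measured by sequencing after poly(A) selection, in 12 libraries: 4 with a scramble hairpin and 4 with each of 2 hairpins against SIDT2, shRNA-B and shRNA-D, all collected 72 h after lentiviral transduction. The authors deposited estimated counts per gene in a single table of 85298 Ensembl identifiers and 12 libraries, with fractional values and no header line on how they were made. Per the submitters' processing notes, fastp and kallisto were used; their versions, the genome build and the annotation are not given in the sources used here, so no coordinates are reported. Estimated counts split reads between transcripts that share sequence. PRDX3, UBE2V2, GJA1 and RPL13A have processed copies in the genome, so their values carry that added uncertainty, and genes that overlap others could share counts as well. Groups and replicate numbers were read from the library titles, and every column of the table matched 1 library by its deposited name.

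A symbol was found for 60443 identifiers. Estimated counts were rounded to whole numbers, library sizes were scaled by TMM, and genes were kept by filterByExpr, which left 26366 tested genes. Totals ranged from 68737402 to 102644699 estimated counts per library. At that depth counting error alone gave SIDT2 a coefficient of variation of 2.14% to 5.03% per library, below the spread between libraries. CPM values are TMM-scaled. edgeR 4.0.16 in R 4.3.3 was used for quasi-likelihood F-tests (glmQLFit with robust shrinkage) in a model of group alone with all 12 libraries, so that the groups shared an estimate of the spread. The contrasts were shRNA-B minus scramble, shRNA-D minus scramble, the mean of both hairpins minus scramble, and shRNA-D minus shRNA-B. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and SE values belong to the fitted log2 fold change. The design text of the series calls the 4 libraries of a condition biological replicates without saying how the cultures were kept apart, so p-values measure the spread between these libraries.

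The test, the contrasts, the named-gene rule, 33 gene lists with 949 entries and the first set of alternatives were fixed before the data were examined. The rule for named genes took SIDT2 first. It then took up to 12 genes per direction called with both hairpins in the same direction, with a mean of at least 5 CPM and no overlap between the 4 scramble and 8 knockdown libraries, ranked by the smaller of both fold changes. For each hairpin it took up to 6 genes per direction that were called there and in the contrast between hairpins. From each list it took up to 4 members with the smallest p for the mean of both hairpins, and SIDT1, RNASET2, LAMP1, LAMP2 and RPL13A were always included. Other list members are named because they were called, and genes that describe the replicate numbers because they differed most clearly, so both were chosen after their values were seen. Some genes, 1 of them taken by the rule, are not reported here. The lists covered lysosome and RNA uptake, autophagy, lipid metabolism, stress responses, mitochondria, RNA metabolism, cell cycle and death, and markers of other cell types. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the 33 lists.

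The replicate numbers 1 to 4 recur in all 3 groups. Deviations from the group means correlated between libraries of the same number with r from 0.140 to 0.619 over all such pairs, all above the threshold of 0.1, against -0.365 to 0.280 between libraries of different numbers, and 11 of the 12 libraries correlated best with their own number. The numbers therefore paired the libraries by the data, although no label says what a number shares. The model with the replicate number as a block was an alternative from the start, and its values stand beside each count. The common biological coefficient of variation was 25.0% without the block and 12.1% with it. No pair of libraries agreed within counting noise: the chi-square per degree of freedom lay between 24.7 and 133.

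Each test was run on simulated counts with the real means, library sizes and dispersions, in which 100 of the 26366 genes were changed by 1.5-fold and 100 by 2-fold. Without the block, 10% (shRNA-B), 13% (shRNA-D) and 35% (mean) of the 1.5-fold genes and 65%, 66% and 72% of the 2-fold genes were recovered, with 0 false calls. With the block, 79%, 80% and 84% and then 94%, 92% and 94% were recovered, with 19, 19 and 17 false calls. Because both contrasts use the same scramble libraries, 20 simulated data sets with no group effect gave the overlap and correlation that sharing alone produces where no gene changes.

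Words of 7 bases in the 3′ UTRs of GENCODE v29 transcripts were tested for a link with lower levels under each hairpin in 12484 genes with a mean of at least 1 CPM; 13882 tested genes had no searched 3′ UTR. For this search each hairpin group, scramble included, was compared with the mean of the other groups. The 4 heptamers with the strongest link per hairpin were chosen on 6242 genes and tested on the other 6242. Planted heptamers were found in 5 of 5 simulated cases. For scramble in the model with the block, 20 shuffles of the test statistic over genes gave a largest absolute z of 4.87. For each gene the transcript with the longest 3′ UTR was searched. The annotation may differ from the one behind the deposited counts. Alternatives were RLE, upper-quartile and total-count scaling, 2 other expression filters, DESeq2 1.42.0, limma voom, the block, fits of only the groups compared, unrounded counts, a minimum fold change of 1.2, libraries left out, and split scramble libraries. Added after the data were seen were the block with DESeq2 and voom, all libraries of a replicate number left out, the split scramble libraries with the block, and the count of shared genes without a scramble-linked heptamer.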

Results

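The transcriptome of HEK 293T cells, a human embryonic kidney line that is readily transduced, was profiled after knockdown of SIDT2, a lysosomal membrane protein known for carrying RNA into lysosomes. Cells received a lentivirus with a scramble control hairpin or with 1 of 2 hairpins against SIDT2, shRNA-B and shRNA-D, and poly(A) RNA was sequenced 72 h later from 4 libraries per group. Library totals lay between 68737402 and 102644699 estimated counts. The purpose stated for the series was to find transcripts controlled through RNA uptake into lysosomes by SIDT2.

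SIDT2 (ENSG00000149577) was lower in all 8 knockdown libraries than in any scramble library, and both hairpins lowered it to a similar level. Scramble libraries 1 to 4 held 21.7, 20.5, 18.3 and 19.7 CPM (20.1 ± 1.42, SD, n = 4). The shRNA-B libraries held 6.61, 8.27, 5.77 and 6.75 CPM (6.85 ± 1.04), and the shRNA-D libraries 5.47, 7.20, 7.58 and 7.55 CPM (6.95 ± 1.0). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was -1.55 ± 0.14 (SE) with shRNA-B (adjusted p = 0.000146) and -1.53 ± 0.14 with shRNA-D (adjusted p = 0.000515). The difference between the hairpins was 0.02 ± 0.14, with a 95% interval of -0.30 to 0.34.

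With both hairpins, 19 genes rose and 2 fell; without shRNA-D replicate 1, 11 rose. Ranked by the smaller of both changes, the first was PRDX3, the mitochondrial peroxiredoxin, which rose from 106 ± 32.4 CPM (SD, n = 4) in scramble cells to 267 ± 39.3 with shRNA-B and 253 ± 49.4 with shRNA-D. PFN2, an actin-binding profilin, rose from 87.6 ± 9.42 CPM to 194 ± 14.2 and 194 ± 9.27, and TMBIM6, a membrane protein of the endoplasmic reticulum that counters cell death, from 238 ± 11.96 to 503 ± 48.0 and 461 ± 43.7. Apart from SIDT2 itself, the gene that fell was INIP, a subunit of a single-stranded DNA-binding repair complex, from 34.1 ± 3.63 CPM to 21.3 ± 2.58 and 21.9 ± 0.37.

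In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PRDX3 changed by 1.33 ± 0.21 log2 with shRNA-B (adjusted p = 0.00861) and 1.252 ± 0.21 with shRNA-D (adjusted p = 0.0258). The values were 1.15 ± 0.09 for PFN2 with each hairpin (adjusted p = 6.34e-05 and 0.000173), and -0.68 ± 0.11 and -0.64 ± 0.11 for INIP (adjusted p = 0.00798 and 0.024). PUDP, a pseudouridine monophosphate phosphatase, rose from 6.96 to 13.3 and 17.1 CPM. The zinc importer SLC39A14 rose from 52.2 to 103 and 97.2 CPM, the endosomal and Golgi SNARE STX6 from 35.3 to 63.3 and 59.4, and the Golgi protein YIPF6 from 49.2 to 88.5 and 76.4. STRADB rose from 36.1 to 61.5 and 66.0 CPM, the Mediator subunit MED14 from 74.4 to 121 and 133, DIXDC1 of Wnt signalling from 15.8 to 29.9 and 26.6, and C3orf38 from 25.5 to 46.5 and 40.9. The 12 genes that the rule took as higher were above scramble in 4 of 4 numbered pairs with each hairpin. The rule itself fixed this, since it asked for no overlap between scramble and knockdown libraries. All 12 carried, in the 3′ UTR, a heptamer linked to lower levels in the scramble libraries, against 23.3% of searched genes not higher with both hairpins. These heptamers were found in the same libraries, partly on genes called here. Of the 12 genes, 6 also carried one linked to shRNA-B and 2 one linked to shRNA-D. INIP carried heptamers linked to shRNA-B and shRNA-D. Single libraries decided the calls of INIP, PRDX3, SLC39A14, STX6 and YIPF6: without scramble replicate 3 the larger adjusted p was 0.0945 for INIP, 0.0838 for PRDX3, 0.0769 for SLC39A14 and 0.0517 for STX6, and without shRNA-D replicate 3 it was 0.0615 for YIPF6.

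**Figure D1:**
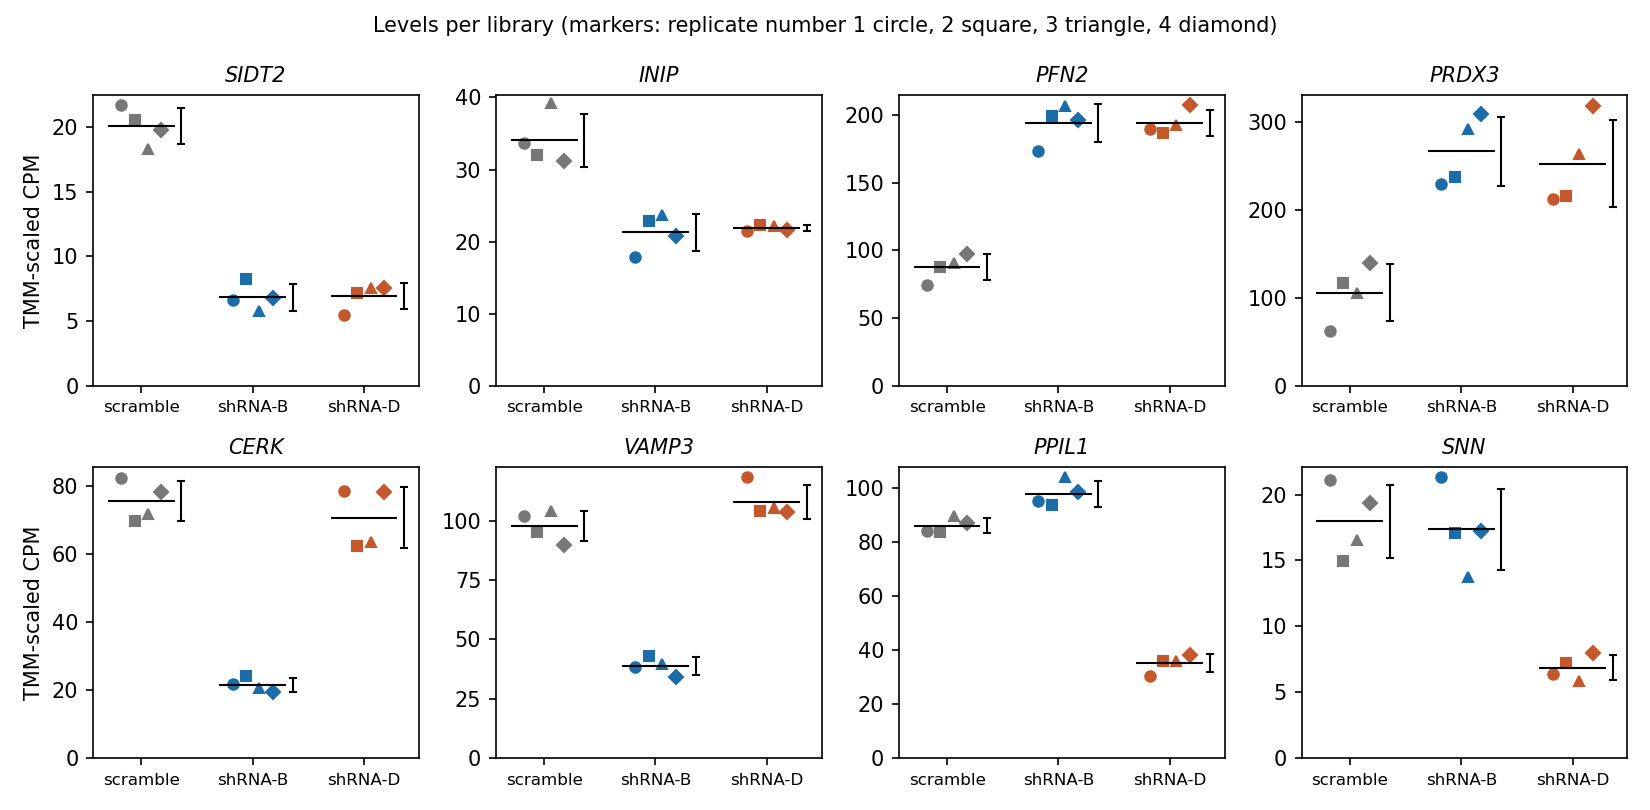
Levels of 8 named genes in each library, in TMM-scaled CPM on a linear axis from 0; markers give the replicate number, horizontal lines the group mean and bars the SD over 4 libraries. SIDT2 and INIP were lower and PFN2 and PRDX3 higher with both hairpins, whereas CERK and VAMP3 were lower with shRNA-B and PPIL1 and SNN with shRNA-D.

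The 21 genes called with both hairpins were set against what shared scramble libraries give. In 20 simulated data sets with no group effect, 0 genes were called with both hairpins in either direction, and independent lists of these sizes would share 0.0468 higher and 0.327 lower genes. These data sets held on average 0.1 calls with shRNA-B and 0.15 with shRNA-D, so an overlap near 0 was fixed in advance. It cannot show what shared scramble libraries give where many genes are called. With the scramble libraries split 2 and 2 between the hairpins in 6 ways, 3 to 11 genes were higher and 1 lower. Across 26366 genes, which are not independent replicates, the fold changes of the hairpins correlated with r = 0.389, below the simulated 0.4995 (0.463 to 0.532) that sharing alone gave. The covariance was 0.0451 against a simulated 0.0705, and with split controls r lay between -0.157 and 0.0136. This simulation held no differences between replicate numbers, and split controls gave each hairpin scramble libraries of other numbers. Neither value can therefore decide whether a change was shared across the transcriptome. With replicate number as a block, 152 genes were higher and 114 lower with both hairpins and 15 went in opposite directions, against 0 opposite without it. Beside these blocked counts, simulation gave 0.1 and 0.45 genes, independent lists 11.1 and 33.0, and split controls 27 to 70 higher and 12 to 58 lower. The simulated overlap was again bound to be small, with on average 2.3 calls with shRNA-B and 1.9 with shRNA-D. The blocked simulation kept the differences between replicate numbers. There r was 0.408 against a simulated 0.497 (0.426 to 0.556), and the covariance 0.0488 against 0.0550 (0.0471 to 0.0649). With split controls the blocked r lay between -0.0762 and 0.0159. The blocked covariance did not exceed the simulated range, so no shared change across the whole transcriptome was detected beyond the shared controls.

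**Figure D2:**
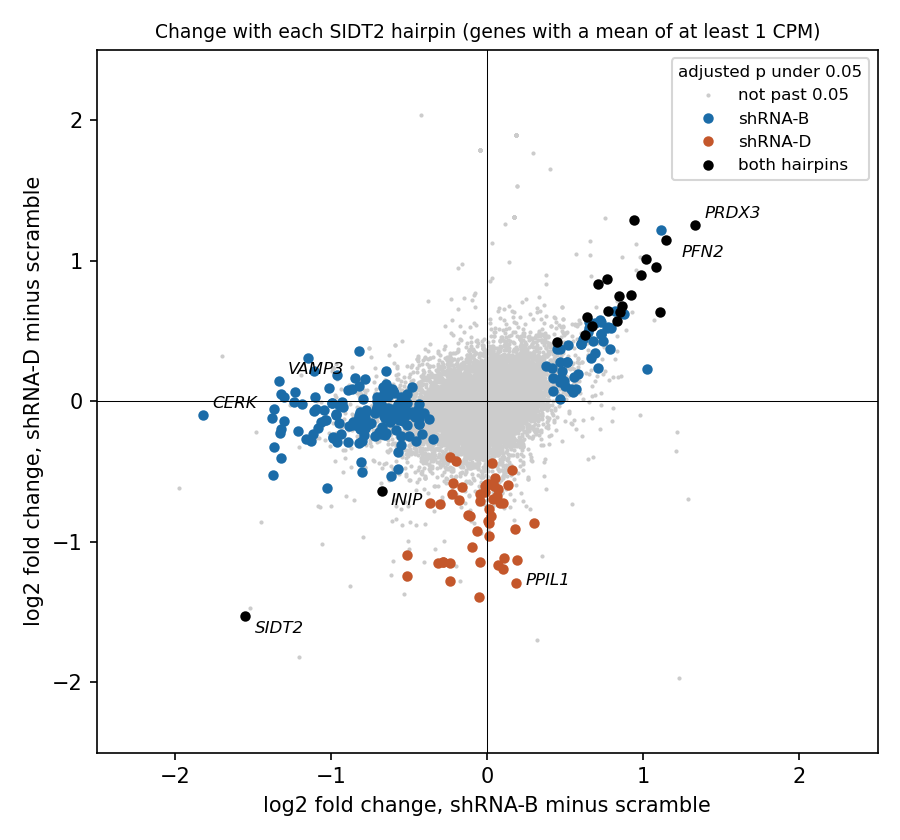
Log2 fold change with shRNA-D against that with shRNA-B for 15869 genes with a mean of at least 1 CPM, of which 2 lie outside the axes; coloured points were called with 1 hairpin and black points with both. Black points lie mainly at the upper right, and calls with 1 hairpin spread along the lower side of each axis.

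For the mean of both hairpins against scramble, 33 genes were higher and 28 lower. Of 31 searched genes among the higher ones, 30 carried a scramble-linked heptamer in the 3′ UTR, against 23.2% of other genes. Of 27 searched lower genes, 18 carried a heptamer linked to shRNA-B, against 20.6%, and 13 one linked to shRNA-D, against 21.4%. These counts include genes used to find the heptamers. CPT2, the mitochondrial carnitine palmitoyltransferase that readies fatty acids for oxidation, rose from 30.8 ± 1.62 CPM to 48.1 ± 4.07 and 46.8 ± 0.97 (mean log2 change 0.62 ± 0.07). CPT2 was also called with each hairpin and carried a scramble-linked heptamer. ATP6V1B2, a subunit of the lysosomal proton pump, rose by 0.58 ± 0.08, from 54.3 ± 1.99 CPM to 90.5 ± 9.28 with shRNA-B and 73.2 ± 5.13 with shRNA-D. The asparagine-specific lysosomal protease LGMN changed by -0.53 ± 0.10, from 57.4 ± 7.29 CPM to 38.6 ± 4.95 and 41.1 ± 3.14. The adjusted p values were 0.00302, 0.00506 and 0.0495 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; that of LGMN was 0.223 without scramble replicate 2. With the block 428 genes were higher and 909 lower for this mean, and the mean also took in genes that fell with 1 hairpin alone, such as CERK. Without scramble replicate 1, 34 genes changed.

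Of the RNA uptake list, SIDT2 alone was called among 12 members for the mean of both hairpins. Its relative SIDT1 lay near the floor, at 1.18 ± 0.26 CPM in scramble, 0.69 ± 0.24 with shRNA-B and 0.95 ± 0.16 with shRNA-D (mean log2 -0.54 ± 0.22, adjusted p = 0.736); with the block its fall with shRNA-B passed (adjusted p = 0.0127). RNASET2, a ribonuclease of the lysosome, was at 28.9 ± 4.85, 32.8 ± 8.82 and 31.3 ± 6.56 CPM (0.15 ± 0.17, adjusted p = 1). LAMP1, an abundant glycoprotein of the lysosomal membrane, was at 64.3 ± 6.96, 90.9 ± 17.5 and 90.1 ± 22.1 CPM (0.49 ± 0.15, adjusted p = 0.357), above scramble in 4 of 4 numbered pairs for each hairpin, and passed with the block (adjusted p = 0.000594). LAMP2 was at 139 ± 6.80, 125 ± 7.82 and 129 ± 7.61 CPM (-0.13 ± 0.07, adjusted p = 0.993), and the ribosomal protein gene RPL13A at 1401, 1545 and 1459 CPM (0.10 ± 0.14, adjusted p = 1). These adjusted p values came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

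Of 56 lysosomal genes, ATP6V1B2 rose, LGMN fell and 54 did not pass for the mean of both hairpins; adjusted over the list alone, 5 were higher and 3 lower. The list median was 0.06 and camera gave an adjusted p of 0.0172, but adjusted p = 0.996 with an estimated correlation. With the block, 8 members rose and 4 fell. Those that rose included the proton-pump genes ATP6V1B2, ATP6V1A, ATP6V0B and ATP6AP1, the chloride-proton exchanger CLCN7, the acid lipase LIPA and LAMP1. Those that fell included the pump subunit ATP6V1C1 and the proteases CTSB and LGMN. In this model ATP6V0B, ATP6AP1, CLCN7, LIPA and ATP6V1C1 were called with shRNA-B and not with shRNA-D. ATP6V1C1 changed by -0.68 log2 with shRNA-B and was higher with shRNA-D than with shRNA-B (0.78). Nuclear-encoded genes of oxidative phosphorylation had a median of 0.08 with 0 of 52 members called in either direction with or without the block (camera adjusted p = 0.00464; adjusted p = 0.996 with an estimated correlation). Genes of the passage from G1 to S had a median of 0.09 with 0 of 30 called, or 2 higher adjusted over the list alone (camera adjusted p = 0.00408; adjusted p = 0.996 with an estimated correlation). With the block 5 of them rose, namely GINS1, E2F1, MCM5, MCM6 and CDC45 of replication licensing and its control. GINS1 and E2F1 were called with each hairpin, and MCM5, MCM6 and CDC45 with shRNA-B and not with shRNA-D. The medians of these 3 lists kept their sign under all 4 scalings, and fry passed none of the 33 lists.

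No other list passed for the mean of both hairpins without the block; with it the heat shock list passed as well, with a median of -0.09 (camera adjusted p = 0.0374; adjusted p = 0.982 with an estimated correlation). In lipid metabolism, 1 of 27 fatty acid oxidation genes (CPT2) rose, 1 of 31 sphingolipid genes (CERK) fell, and 0 of 24 cholesterol and 0 of 35 fatty acid storage genes were called. With the block, 1 sphingolipid gene rose and 3 fell, HSD17B4, EHHADH and PPARD of fatty acid oxidation fell beside the rise of CPT2, and FADS1, SCD5 and LPIN1 of storage were called, the last of them higher. In this model CERK, EHHADH, FADS1 and SCD5 were called with shRNA-B and not with shRNA-D, and LPIN1 with shRNA-D and not with shRNA-B. Among stress lists, PRDX3 rose alone of 23 antioxidant genes. In those for heat shock (19 members), the unfolded protein response (25), the integrated stress response (31), NRF2 (21), p53 (27), hypoxia (31), immediate early genes (27), NF-kB (15), interferon (31), BCL2-related factors (28) and autophagy (38), 0 members were called. With the block, WIPI2, GABARAPL2 and MAP1LC3B of autophagosome formation rose and UVRAG fell. All were called with shRNA-B, and of them WIPI2 alone with shRNA-D. The blocked model also called, as higher and lower, 1 and 2 genes of the unfolded protein response, 0 and 2 of the integrated stress response, 0 and 3 p53 targets, 2 and 2 of hypoxia and 1 and 3 BCL2-related factors, beside 1 higher gene each of NRF2 and interferon. Lists of RNA decay (48), small RNA factors (14), nuclear RNAs (11), snoRNA hosts (37), histones (22), ribosomal proteins (78), mitochondrial transcripts (13) and G2/M genes (31) also held 0 calls, as did markers of fibroblasts (10), leukocytes (8), epithelium (6), hepatocytes (3) and neurons (14). With the block, TNRC6B, TNRC6C and AGO4 of microRNA silencing fell, 1 RNA decay gene rose and 1 fell, and 1 G2/M gene fell. TNRC6C and AGO4 were called with shRNA-B and not with shRNA-D, and TNRC6B with shRNA-D and not with shRNA-B. Of the markers, the fibroblast genes FBN1 and LOX fell, and 3 neuronal genes rose and 2 fell. These marker genes were called with shRNA-B and not with shRNA-D. Without the block the camera adjusted p was 0.127 for heat shock, 0.676 for antioxidant, G2/M, interferon, p53 and ribosomal protein genes, 0.725 for autophagy, fibroblast and NF-kB genes, and 0.994 for the remaining 21 lists. Over all lists, 3 members were called higher and 3 lower, against 31 and 35 with the block. Median and mean differed in sign for 8 of the 33 lists, and median and camera direction for 11.

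With shRNA-B, 65 genes rose and 166 fell, of which 8 and 36 changed by over 2-fold. Of 59 searched genes that rose, 49 carried a scramble-linked heptamer, against 23.1% of other genes. This count includes genes used to find the heptamers. CERK, the ceramide kinase, fell most among the named genes, from 75.5 ± 5.90 CPM (SD, n = 4) to 21.4 ± 2.07, against 70.7 ± 8.98 with shRNA-D. VAMP3, a SNARE of recycling endosomes, fell from 97.8 ± 6.47 to 38.7 ± 3.69 CPM, and FECH, the ferrochelatase that completes heme, from 49.2 ± 4.37 to 19.0 ± 2.72. UHMK1, a serine/threonine kinase, rose from 103 ± 14.1 to 210 ± 49.4 CPM, against 121 ± 4.49 with shRNA-D.

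The log2 changes with shRNA-B were -1.82 ± 0.11 for CERK (adjusted p = 8.53e-06), -1.34 ± 0.09 for VAMP3 (adjusted p = 1.96e-05), -1.37 ± 0.11 for FECH (adjusted p = 6.34e-05) and 1.03 ± 0.15 for UHMK1 (adjusted p = 0.0042) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The ubiquitin-conjugating enzyme variant UBE2V2 fell from 128 to 49.3 CPM, the glycolipid transfer protein GLTP from 43.4 to 16.8 and the G protein subunit GNAL from 31.0 to 12.02. RRAGC, a Rag GTPase that brings mTOR complexes to lysosomes, rose from 26.9 to 39.5 CPM and ARL2BP from 54.4 to 75.0. Both calls were lost without scramble replicate 2 (adjusted p = 0.0705). CERK, UBE2V2, FECH and GNAL carried a heptamer linked to shRNA-B in the 3′ UTR, and VAMP3 and GLTP carried none. CERK and GLTP carried one linked to shRNA-D. Among searched genes not lower with shRNA-B, 20.1% carried a shRNA-B heptamer, and these heptamers were found in the same libraries. Of the genes that rose, UHMK1 and RRAGC carried heptamers linked to shRNA-B, to shRNA-D and to scramble, and ARL2BP carried none of these. GLTP and GNAL were also lower with shRNA-D in the blocked model alone (adjusted p = 0.00751 and 0.00987, against 0.0863 and 1 without it). Lysosomal members that changed included ATP6V1B2, higher, and ATP6V1C1, CTSB and LGMN, lower, with 51 of 56 not past the threshold. FADS1, a fatty acid desaturase, fell by 1.30 on the log2 scale, from 142 to 57.4 CPM, and BMF, PRC1, TNRC6C and FBN1 fell as well. Camera passed the lysosome (adjusted p = 0.00454), oxidative phosphorylation (2.03e-06) and G1/S lists (0.000186), all with medians above 0; the values were adjusted p = 0.959, 0.959 and 0.683 with an estimated correlation. With the block, 1064 genes were higher and 1461 lower, and 7 lists passed, none of them with an estimated correlation (lowest adjusted p = 0.236). Cholesterol synthesis and snoRNA hosts joined the 3 above, and p53 targets (camera adjusted p = 0.0140) and fibroblast markers were lower. The fibroblast markers had a median of -0.31 with 5 of 10 lower (camera adjusted p = 0.000294), and fry passed this list alone (adjusted p = 0.00195). Without scramble replicate 2, 32 genes were higher and 88 lower.

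With shRNA-D, 19 genes rose and 52 fell, of which 4 and 17 changed by over 2-fold. All 19 that rose also rose with shRNA-B, so the rule named no gene higher with shRNA-D alone. SNN, a small membrane protein, fell from 17.98 ± 2.77 CPM (SD, n = 4) to 6.85 ± 0.97, against 17.4 ± 3.09 with shRNA-B. PPIL1, a peptidyl-prolyl isomerase of the spliceosome, fell from 86.1 ± 2.87 to 35.2 ± 3.41 CPM, and GJA1, the main connexin of gap junctions, from 46.5 ± 9.95 to 20.3 ± 3.78.

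The log2 changes with shRNA-D were -1.39 ± 0.16 for SNN (adjusted p = 0.00178), -1.29 ± 0.09 for PPIL1 (adjusted p = 2.57e-05) and -1.20 ± 0.19 for GJA1 (adjusted p = 0.0186) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The caveolin CAV2 fell from 10.6 to 4.38 CPM, C6orf120 from 65.9 to 29.4, and ATP2B1, a calcium pump of the plasma membrane, from 146 to 65.6. All 6 named genes lower with shRNA-D carried a heptamer linked to it in the 3′ UTR, against 21.3% of searched genes not lower with it. These heptamers were found in the same libraries. CAV2 and GJA1 also carried one linked to shRNA-B, and GJA1 and ATP2B1 one linked to scramble. GJA1 and ATP2B1 lost their calls without scramble replicate 3 (adjusted p = 0.0584 and 0.0506). Of list members, CPT2 and PRDX3 rose, and SPTLC1 of sphingolipid synthesis and ANLN of cytokinesis fell. SPTLC1 fell by 0.91 on the log2 scale, from 88.1 to 47.0 CPM, and ANLN by 1.13, from 173 to 79.0 CPM. Camera passed the heat shock list alone, with a median of -0.14 over 19 genes (-0.0898 with library totals) and 0 called (adjusted p = 0.00547; adjusted p = 0.839 with an estimated correlation). With the block, 276 genes were higher and 595 lower and 1 list, heat shock, passed, but not with an estimated correlation (adjusted p = 0.938). Without shRNA-D replicate 1, 11 genes were higher and 21 lower.

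The contrast between the hairpins, which takes no scramble library, called 123 genes higher and 128 lower with shRNA-D than with shRNA-B. All 15 genes named for a single hairpin were among them. CERK differed by 1.72 ± 0.11 log2 (adjusted p = 5.45e-06), VAMP3 by 1.48 ± 0.09 (adjusted p = 5.45e-06) and FADS1 by 1.34, all higher with shRNA-D. PPIL1 differed by -1.47 ± 0.09 (adjusted p = 4.96e-06), ANLN by -1.32 and SPTLC1 by -1.09, all lower with shRNA-D, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

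Of the 33 lists, 8 differed between the hairpins in camera (adjusted p from 1.6e-05 to 0.0246), none of them with an estimated correlation (adjusted p = 0.693). Lower with shRNA-D were cholesterol synthesis (median -0.17), snoRNA hosts (-0.16), the unfolded protein response (-0.13), oxidative phosphorylation (-0.10), G1/S (-0.08) and RNA decay (-0.07). Higher were p53 targets (0.15) and fibroblast markers (0.34). Each of these medians kept its sign under all 4 scalings, but with library totals, where the median of all genes was 0.0544 instead of -0.00466, those that were lower shrank to -0.113 (cholesterol), -0.0945 (snoRNA hosts), -0.0647 (unfolded protein response), -0.0346 (oxidative phosphorylation), -0.0176 (G1/S) and -0.0108 (RNA decay). Over all lists, 8 members were higher and 9 lower. In the direction of their lists went NDUFB10 of oxidative phosphorylation and MCM4 and RRM2 of G1/S, all lower with shRNA-D, and the fibroblast marker FBN1, higher. Against it went MVK of cholesterol synthesis, higher, and CCNG1 of the p53 list, lower; the nuclear RNA NORAD and the glycolytic PFKM, of lists that did not pass, were lower. With the block, MSMO1, SQLE, CYP51A1 and INSIG1 were among 12 cholesterol genes lower with shRNA-D, beside 2 higher, and CDKN1A, MDM2, GDF15, ZMAT3 and TP53I3 among 8 p53 targets that were higher, beside 2 lower. With the block 1558 genes were higher and 1833 lower, and 12 lists passed, none of them with an estimated correlation (lowest adjusted p = 0.153). In this model fry passed fibroblast markers (adjusted p = 0.00082), cholesterol (adjusted p = 0.0367) and hypoxia (adjusted p = 0.0498). Without shRNA-D replicate 1, 113 genes differed.

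Libraries with the same replicate number deviated from their group means together, most clearly for numbers 1 and 4. The first principal component (24.1% of variance) set number 4 apart and the second (18.8%) number 1, in all 3 groups, and 12457 of 26366 genes differed between numbers. In libraries of number 4 the receptor kinase DDR2 was at 6.98 CPM, against 100, 149 and 158 in numbers 1 to 3, and BEX1 at 3.17 against 54.9, 50.7 and 54.2. The neurofilament NEFM was at 104 CPM in number 4, against 4.74, 17.1 and 16.6. Numbers 2 and 3 lay above 1 and 4 in lists for hypoxia (median log2 0.78), immediate early genes (0.70) and the integrated stress response (0.54). In those libraries VEGFA was at 129 and 121 CPM, against 38.7 in number 1 and 72.1 in number 4, and MYC at 229 and 217 against 62.8 and 99.6. Fibroblast and epithelial markers were lower in number 4 by medians of -0.50 and -0.57. Each number held 1 library of every group, so these differences were spread over the 3 groups.

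**Figure D3:**
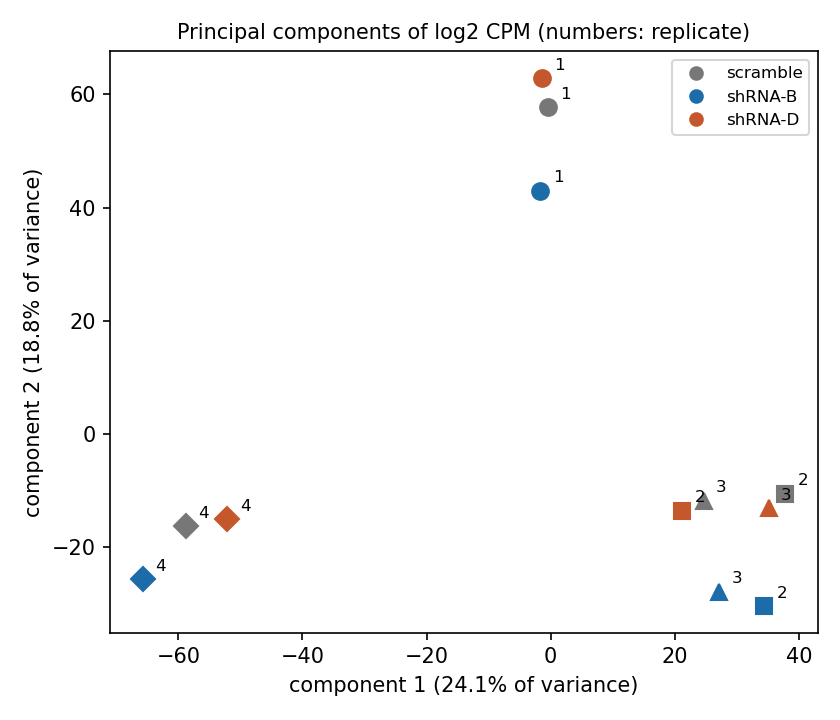
First and second principal components of log2 CPM for the 12 libraries, coloured by group and marked by replicate number. Libraries of number 4 lie at the left and those of number 1 at the top, whatever their group.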

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

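The splits of the libraries, the heptamer tests and the tests on replicate number 4 in this part were chosen only after the results were seen.

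With both hairpins 19 genes were higher and 2 lower, and a candidate explanation is an action of the scramble hairpin itself on 3′ UTRs. Outside the genes used to find its heptamers, 7 of 7 searched genes that were higher with both hairpins carried a scramble-linked heptamer, against 23.6% of other genes (Fisher's exact test, 2-sided, p = 4.19e-05). By the same test, a loss of SIDT2 that acts without regard to these heptamers is argued against, since 0 of the 7 lacked one; an action of SIDT2 on transcripts with these heptamers stays open, because scramble was the only control. Among the genes not used to find the heptamers, differences in scramble were small in the blocked model. They were -0.0664 ± 0.0108 log2 (SE) and -0.0503 ± 0.0115 for the scramble heptamers ranked 1 and 2. For those ranked 3 and 4 they were -0.00788 ± 0.00932 and 0.00197 ± 0.00783, though z adjusted for 3′ UTR length was -6.74 and -6.88. Fisher's test took no account of that length. Shared scramble libraries are argued against as the whole cause, since every way of splitting them left at least 3 shared higher genes. In the blocked model 27 of 133 searched higher genes and 18 of 108 lower ones carried none of the linked heptamers in the 3′ UTR, against 6912 of all 12484 searched genes. Both shares lay below that of all searched genes. Calls that go with the heptamers lower these shares whether or not SIDT2 also acts, and the genes used to find the heptamers were counted here. These counts therefore neither show nor exclude a response to SIDT2 itself.

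The genes lower with 1 hairpin and different from the other form another pattern, and it may reflect sites of that hairpin in other transcripts. Outside the genes used to find the heptamers, 60 of 76 genes lower with shRNA-B carried a heptamer linked to shRNA-B (p = 7.88e-28, Fisher's exact test, 2-sided) and 18 of 20 lower with shRNA-D a heptamer linked to shRNA-D (p = 8.52e-11). A large difference in the depth of knockdown at the RNA level is argued against as the cause. SIDT2 RNA differed between the hairpins by 0.0203 on the log2 scale (95% interval -0.296 to 0.337). A smaller difference lies within this interval, and SIDT2 protein was not measured here, so knockdown depth is not excluded. The hairpin sequences were not analysed here, so whether the linked heptamers match the guide strands was not tested. In the blocked model the first shRNA-B heptamer was also linked to lower levels when it lay upstream of the 3′ UTR (z = -20.3). For the first shRNA-D heptamer z was -7.49 there, and for the first scramble heptamer -1.36. SIDT2 itself held heptamers linked to shRNA-B and to shRNA-D upstream of its 3′ UTR. VAMP3 and GLTP fell with shRNA-B without a shRNA-B heptamer in the 3′ UTR, so for them sites elsewhere in the transcript or effects further downstream stay open.

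Libraries of replicate number 4 stood apart in every group. Low depth is argued against by 14 genes with a mean of at least 5 CPM that lay over 4-fold apart. Fibroblasts mixed into numbers 1 to 3, a possible source of DDR2, are argued against by COL1A2, an abundant fibroblast transcript, which reached at most 0.138 CPM there, against 0.165 in number 4. Another stock of cells or another culture day for number 4 could account for it, since its 3 libraries moved together (lowest correlation of deviations 0.516), but no label names stocks or days, so these cannot be told apart. No group of the design explains it, and no biological explanation was tested.

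Whether chance could group the libraries so was examined by refitting other splits. For shRNA-B, 1 of 35 splits of the 8 libraries, the real one, gave as many as 231 genes, and the highest other gave 2. For shRNA-D the figures were 1 of 35, 71 genes and 3, and for the contrast between hairpins 1 of 35, 251 genes and 241. That last other split set numbers 1 and 4 against 2 and 3, and it points to the structure by replicate number. Among splits that part all 4 numbered pairs, 8 in each comparison, the highest other counts were 1, 0 and 0. For the mean of both hairpins 4 of 100 splits gave as many as 61 genes, with 351 as the highest other; the 3 larger ones gathered all libraries of number 1 or of number 4, and 3 other splits that part all numbers gave at most 0. For genes shared by both hairpins the figures were 2 of 100, 21 genes and 68. With the block and relabelling within numbers they were 3 of 100, 266 genes and 946; both larger draws kept the 4 shRNA-B libraries together as the reference. Over splits drawn without regard to number, or within numbers for the last count, the share was under 0.05 for each of the 6 counts. Only the relabelling within numbers kept the structure of the real groups. Splits drawn without regard to number lack that structure, so they cannot exclude chance for the other counts. The 8 splits that part all 4 numbered pairs are too few for a share under 0.05, so they cannot exclude it either.

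In 7 of 105 groups of 4 libraries a library lay outside the others, where chance gives about 1 in 20. TMBIM6 was at 527 CPM in shRNA-D replicate 1 (others 434 to 445), STRADB at 26.3 in scramble replicate 1 (38.3 to 40.2), STX6 at 49.3 in shRNA-B replicate 4 (66.4 to 69.9) and VAMP3 at 118 in shRNA-D replicate 1 (104 to 105). C6orf120 was at 81.5 CPM in shRNA-B replicate 3 (64.1 to 66.3), SIDT1 at 1.05 in shRNA-B replicate 1 (0.555 to 0.580) and LAMP2 at 113 in shRNA-B replicate 2 (127 to 130).

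The 251 genes that differed between the hairpins included every gene named for a single hairpin. Lower with shRNA-D than with shRNA-B were UHMK1 (-0.80 log2), RRAGC (-0.48), ARL2BP (-0.45), SNN (-1.34), PPIL1 (-1.47), CAV2 (-1.04), GJA1 (-1.29), C6orf120 (-1.23) and ATP2B1 (-0.84). Higher were CERK (1.72), UBE2V2 (1.26), GLTP (0.85), FECH (1.31), GNAL (1.04) and VAMP3 (1.48). List medians that differed were -0.13 for the unfolded protein response, -0.17 for cholesterol, -0.10 for oxidative phosphorylation, -0.16 for snoRNA hosts, -0.0773 for G1/S, -0.0722 for RNA decay, 0.15 for p53 targets and 0.34 for fibroblast markers; none of these held with an estimated correlation (adjusted p = 0.693).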

How the results depend on the processing

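The block with DESeq2 or voom, leaving out all libraries of a number, split controls with the block and the count without scramble heptamers were tests chosen only after the results were seen. SIDT2 fell with both hairpins under every alternative except the split scramble libraries, for which its change was not computed. None of the alternatives checked for named genes reversed one. Fits without all libraries of a number, with or without the block, and split scramble libraries were not checked for named genes. Named genes gave 483 outcomes, in which all fits with a single library left out counted once per gene. Of these outcomes 31 ended a call, 4 gained one and 448 left the call, or the lack of one for 5 of the 36 genes, as it was. Counts are given in the order higher and lower with shRNA-B (65 and 166), higher and lower with shRNA-D (19 and 52), higher and lower with both (19 and 2), mean of both hairpins (61) and between hairpins (251). With the replicate block they were 1064, 1461, 276, 595, 152, 114, 1337 and 3391; all genes called without it were called with it, the spread fell from 25.0% to 12.1%, and of the 36 named genes it changed the call of 1, LAMP1, in the comparison it was named for. With the block in DESeq2 the counts were 1335, 1700, 444, 811, 215, 178, 1894 and 3568, and r between the hairpins was 0.482; with the block in voom they were 1076, 1590, 291, 604, 153, 117, 1429 and 3589. DESeq2 without the block gave 233, 430, 83, 178, 56, 14, 341 and 815, and a minimum fold change of 1.2 gave 20, 59, 5, 14, 5, 1, 20 and 71. Fits of only the groups compared gave 20 and 70 with shRNA-B, 1 lower with both and 108 between hairpins. The mean of both hairpins gave 94 genes with upper-quartile factors, 97 with library totals, 110 without a filter and 131 with at least 1 CPM in 4 libraries. Library totals gave 31 higher with shRNA-D; the 1 CPM filter gave 106 higher with shRNA-B, 29 higher with shRNA-D and 390 between hairpins; r was 0.481 without a filter. Of the lists for the mean of both hairpins, 3 passed with camera, 0 with an estimated correlation and 0 with fry. Split scramble libraries left medians of 4 higher and 1 lower shared genes, or 57 and 24.5 with the block, where each hairpin had fewer controls and shared none of them; among genes with a searched 3′ UTR (18 shared higher and 2 lower, or 133 and 108 with the block), 0 and 2 were left without scramble-linked heptamers, or 29 and 75 with the block. For the other changes the cause was not tested.

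Leaving out single libraries, all libraries of a number, or a number in the blocked model gave 17 to 939 and 36 to 1605 genes with shRNA-B, 5 to 274 and 8 to 641 with shRNA-D, 4 to 147 and 1 to 112 with both, 13 to 1339 for the mean, 49 to 3496 between hairpins, r from 0.320 to 0.584 and 1 to 5 lists. With single libraries left out the ranges were 32 to 75 and 88 to 186, 11 to 21 and 21 to 56, 11 to 20 and 1 to 3, 34 to 91, and 113 to 310. Genes higher with shRNA-B were 37, 32, 41, 34 and 43 without scramble replicates 1, 2 and 3 and shRNA-B replicates 1 and 3, and genes lower 110, 88, 89 and 89 without the first 4 of these. Genes lower with shRNA-D were 32, 27 and 22 without scramble replicates 1 to 3 and 21, 29, 25 and 34 without shRNA-D replicates 1 to 4. Without shRNA-D replicate 1, 11 genes were higher with shRNA-D and 11 with both. The mean gave 34 and 36 genes without scramble replicates 1 and 2, and the hairpins differed in 137 and 154 genes without shRNA-B replicates 1 and 3 and in 113, 119 and 129 without shRNA-D replicates 1 to 3. Without all libraries of number 4 the counts were 21, 77, 5, 17, 5, 1, 13 and 105, and in the blocked model 613, 1011, 147, 412, 81, 78, 806 and 2276.

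Among named genes, left-out libraries ended calls of LGMN (10 of 12 libraries, adjusted p = 0.0845 to 0.223), INIP (7, 0.0521 to 0.0945), SLC39A14 (6, 0.0564 to 0.0895), STX6 (6, 0.0517 to 0.0669), ARL2BP (5, 0.0601 to 0.082), PRDX3 (4, 0.0583 to 0.0838), RRAGC (4, 0.0564 to 0.0705), ATP2B1 (3, 0.0506 to 0.053), GJA1 (3, 0.0508 to 0.0584) and YIPF6 (2, 0.0563 to 0.0615) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scramble replicate 3 ended 9 of these calls, shRNA-D replicate 1 ended 7 and shRNA-B replicate 2 none. The minimum fold change of 1.2 ended 14 calls among the 36 named genes. Depth of 68737402 to 102644699 counts did not limit genes of this abundance, but SIDT1, near 1 CPM, was measured with few counts.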

Other observations

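The genes in this part were picked, and the search for transcripts free of the linked heptamers was chosen, only after the results were seen.

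With the block, 12 genes were higher and 5 lower with both hairpins although the searched transcript held none of the 12 linked heptamers anywhere. Only the transcript with the longest 3′ UTR was searched for each gene. These genes came from 3513 searched genes without any such heptamer, while 133 were higher and 108 lower among all 12484 searched genes. Those that rose included LAMP1 of the lysosomal membrane (mean log2 change 0.47 ± 0.06), the transcriptional repressor CBX7 (0.44 ± 0.06), RNH1, the cytosolic inhibitor of pancreatic-type ribonucleases (0.35 ± 0.05), SNX12 (0.31 ± 0.05) and E2F1 (0.30 ± 0.05). RNH1 stood at 22.4 ± 1.84 CPM (SD, n = 4) in scramble, 31.0 ± 3.06 with shRNA-B and 26.3 ± 2.48 with shRNA-D. Those that fell were KLHL11 (-0.54 ± 0.06), the sphingosine kinase SPHK1 (-0.39 ± 0.08), SLAIN1 (-0.35 ± 0.05), the acyltransferase MBOAT1 (-0.32 ± 0.06) and SEPHS1 (-0.23 ± 0.05). Each gene kept its direction in 4 of 4 numbered pairs with either hairpin, which selection by the blocked model favours and which adds no separate support. Only 1 of these 17, KLHL11, passed without the block for the mean of both hairpins (adjusted p = 0.0315 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). As they were picked from the results, these genes are a short list to measure again with other hairpins, not a set of established targets.

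Several genes varied by replicate number far more than by hairpin. FBXL16 stood at 1.94 CPM in number 4, against 23.9, 31.9 and 25.8 in numbers 1 to 3. KRT8 was at 7.22 CPM in number 4, against 35.1, 37.4 and 34.9. IGF2 was at 21.7 CPM in number 1, against 5.76, 5.45 and 2.03, while NDRG1 and PDK1, genes raised by low oxygen, were at 162 and 147 CPM in number 2 and at 30.6 and 45.5 in number 1.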
